A study of Mus musculus with 5 samples.

How the data were processed

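The data are CpG methylation calls from bisulfite-sequenced genomic DNA of mouse sperm, with 3 libraries of mice aged 2 months and 2 of mice aged 18 months. Groups and replicate numbers came from the labels. Per the submitters' processing notes, the tools were Trim Galore 0.4.3, Bismark 0.16.3 and methylKit 1.4.0, with the mm10 (GRCm38) build; their settings, and whether duplicate reads were removed, are not given in the sources used here. The deposited files list, per the file headers, the coverage as a count of reads for each cytosine and strand, with the percent of those reads read as C (methylated) and as T (unmethylated). The lowest coverage in each of the 5 files was 5 reads, so the authors' lists leave out cytosines below it. Percent times coverage gave a whole number of reads, within the rounding of the listed percent, for 100% of the listed cytosines. Bisulfite reads do not separate methylation from incomplete conversion, nor a C-to-T variant from an unmethylated C, and aligned reads from near-identical copies can add to one place.

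Reads of both strands of a CpG were summed. The common set held CpGs with at least 10 reads in all 5 libraries and none above the 99.9th percentile of coverage of its library. It favours places of high coverage: mean coverage there was 32.6 to 43.0 reads per library, while over all listed CpGs it was 11.6 to 14.1. Counts were summed over 1000-bp tiles with at least 3 common CpGs on chromosomes 1 to 19, X and Y. The median tile had 114 to 159 reads in a library. Unplaced sequences held 2.68% to 3.80% of reads and were not used.

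Gene coordinates came from a RefSeq table of the same build that has no strand, exons or sequence. True promoters, UTRs, exons and introns, CpG islands and repeats were therefore not analysed here. In place of promoters, windows of 1000 bp either side of both ends of 34614 protein-coding and lncRNA genes were used, and for the lists the less methylated measured end by reads pooled over all libraries. The 15 lists were maternally imprinted loci, paternally imprinted loci, germline gene promoters, spermatid, leukocyte, epididymal epithelium and housekeeping genes, developmental regulators, neurodevelopmental and autism genes, synaptic and neuronal genes, insulin and metabolic genes, DNA methylation machinery, clustered protocadherins, olfactory receptors and vomeronasal receptors. All but 1 of their symbols matched the table.

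Group means were compared with two-sided exact permutation tests over the 10 splits of 5 libraries. Each tile, CpG, gene end or gene region was tested with a quasi-binomial logistic model of methylated and unmethylated reads, old against young, with a dispersion moderated across features as in limma's squeezeVar and not let under 1, and Benjamini-Hochberg adjustment. A call needed an adjusted p under 0.05 and a difference of at least 10 points. The prior of the dispersion came from all features for tiles, ends and regions. For single CpGs it came from those with an expected binomial variance of at least 2, since on simulated data the other prior recovered 0 of 200 changed CpGs at each size. This choice was made on simulated data after the design was fixed. For tiles that narrower prior made 18 calls in simulated data with no change and was not used. Each prior was tried on counts simulated with the dispersion that it gave itself. These trials therefore do not show which prior suits the data. Tests were checked on simulated data with 200 changed features. Those features were among the more methylated and were lowered in old sperm, so gains were not simulated. Simulated libraries varied independently at each feature, without a departure of a library across many features. Lists were tested with camera of limma 3.58.1 in R 4.3.3, with a preset correlation of 0.01, on log2((methylated + 1)/(unmethylated + 1)). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads are not independent molecules, so intervals, where given, cover counting error only.

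The design, lists and first alternatives were fixed before the data were examined. With fewer than 10 called tiles, the rule for named tiles took the 5 higher and 5 lower with the smallest p, and for each list up to 3 members with the largest difference. One of the tiles so chosen, and the called CpGs in it, are not reported here. Alternatives covered the dispersion model, limma, the coverage minimum (20 and 5 reads) and its upper limit, thresholds, tile width, the gene-end window (2000 bp outside to 500 bp inside), the set of CpGs, autosomes only, each library left out and the replicate number. Gene regions, every listed CpG for the lists, the other dispersion prior, the germline list as a covariate, leaving out both young replicates 2 and 3, and leaving out the chromosome 8 stretch were added after seeing the data. When a library was left out, the common CpGs of all 5 were kept.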

Results

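DNA methylation was measured by whole-genome bisulfite sequencing in sperm that had swum out of the cauda epididymis, the tail of the duct in which sperm are stored, of C57BL/6 mice. The libraries comprised 3 from mice aged 2 months (young replicates 1 to 3) and 2 from mice aged 18 months (old replicates 1 and 2). The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these libraries. Reads over the listed CpG cytosines summed to 84117315, 67774094 and 97769462 in young replicates 1 to 3 and to 90716510 and 90640296 in old replicates 1 and 2. Each listed cytosine had at least 5 reads, with a median of 6 or 7. Of 13063725 CpGs listed in any library, 975172 had at least 10 reads in all 5 and lay under the upper coverage limit. At these CpGs the median was 22 to 32 reads per library, so the results below describe a well-covered 7.46% of the listed CpGs.

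The first question was whether the overall methylation level of sperm differed between ages, and it did not do so by more than the replicate spread. Mean CpG methylation was 88.6% ± 0.441 (SD, n = 3) in young and 88.9% ± 0.0683 (SD, n = 2) in old sperm, a difference of 0.233 points (two-sided exact permutation test, p = 0.8). Gene bodies were at 91.2% in young and 91.4% in old libraries, and intergenic CpGs at 88.0% and 88.3%. Without young replicate 3 the difference of old minus young turned to -0.334 points in gene bodies, -0.0834 on the autosomes and -0.0186 overall. CpGs within 1000 bp of an annotated gene end were less methylated than both, at 70.6% ± 0.248 in young and 70.7% ± 0.177 in old sperm. Their difference of 0.0978 points was 0.497 when weighted by coverage and 1.09 at every CpG a library covers, where the young SD was 0.498 and 0.804 (exact permutation tests, p = 0.3 and 0.2). With 1 library left out it lay between -0.0272 points (without old replicate 2) and 0.241 (without young replicate 3). The X chromosome was at 85.1% and 85.7%. The Y chromosome had the lowest level of any chromosome and the largest difference between the ages, at 59.7% ± 2.24 (SD, n = 3) in young and 62.3% ± 1.07 (SD, n = 2) in old sperm (exact permutation test, p = 0.3), and young replicate 3, at 61.9%, lay above old replicate 2, at 61.6%. The 10 possible splits of 5 libraries allow no exact p under 0.1, and after Benjamini-Hochberg adjustment over the classes every p was 1.

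**Figure D1:**
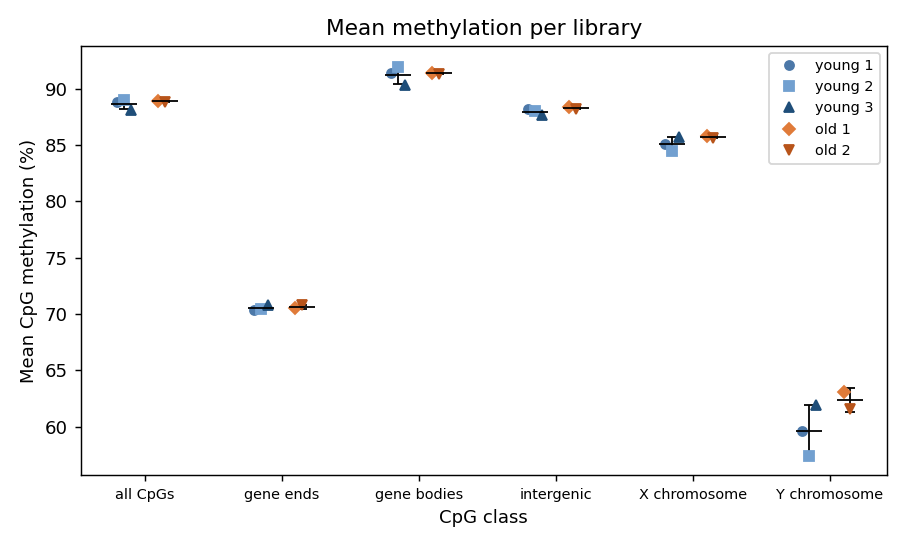
Mean CpG methylation (y axis, percent, not starting at 0) by CpG class (x axis). Each symbol is a library, horizontal lines are group means and bars are SDs (n = 3 young, n = 2 old); on the Y chromosome the young libraries spanned 57.4% to 61.9% and the old ones 61.6% to 63.1%.

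The libraries that differed most from each other were both young. Across 134735 tiles of 1000 bp, the correlation of tile methylation was 0.903 between young replicates 2 and 3, the lowest of the 10 pairs of libraries, and 0.956 between the old replicates. These values are across tiles, which are not independent replicates. In the 1954 tiles with a mean of 20 to 40% in old sperm, methylation was 31.1% in young replicate 1, 25.6% in young replicate 2 and 42.6% in young replicate 3, against 30.6% and 32.6% in the old replicates. In tiles at 90 to 95% the order was turned, at 93.6%, 94.1% and 91.9% in young replicates 1 to 3. The first principal component, with 45.9% of the variance, placed young replicates 2 and 3 at its ends and the other 3 libraries between them. The next component, with a smaller share of the variance, placed the ages apart. Its scores were 2.152, 0.404 and 0.628 in young replicates 1 to 3 and -1.579 and -1.605 in old replicates 1 and 2. This separation was not tested.

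**Figure D2:**
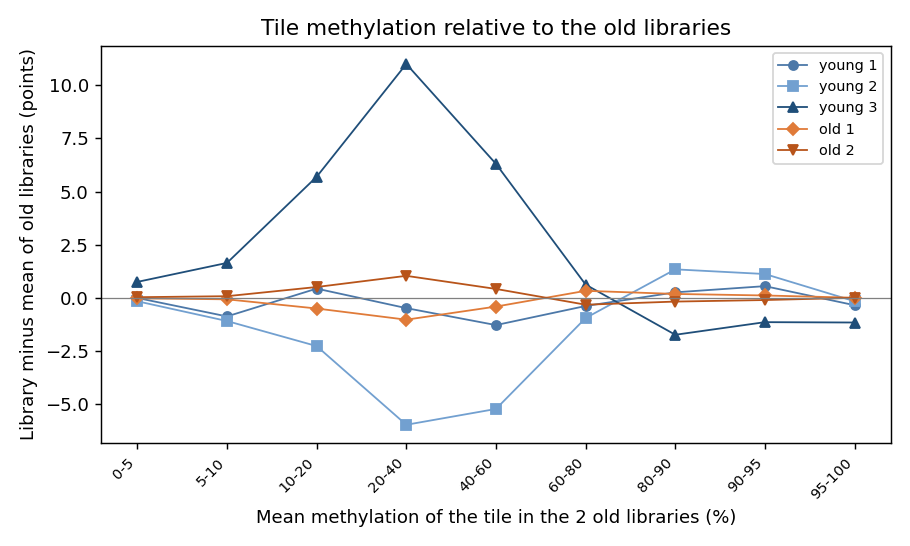
Tile methylation of each library minus the mean of the 2 old libraries (y axis, percentage points) in tiles grouped by their mean in the old libraries (x axis, percent). Young replicates 2 and 3 depart in opposite directions in tiles at 20 to 40%, where they lie at 25.6% and 42.6%, and young replicate 1 stays near the old libraries.

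The study set out to examine regions that differ in methylation between young and old sperm. No tile passed the test (quasi-binomial model with limma-type moderated dispersion, adjusted p under 0.05 and a difference of at least 10 points). The smallest adjusted p was 0.458, and 3721 tiles, 2.76% of those tested, had an unadjusted p under 0.05, of which 2231 were higher and 1490 lower in old sperm. limma on the log2 odds likewise called 0 tiles, with 5210 at an unadjusted p under 0.05. In simulated data the test recovered 56.5% of tiles lowered by 20 points in old sperm and 77.5% of those lowered by 30 points. Gains were not simulated. Of the unchanged tiles there, 4.92% and 4.97% had an unadjusted p under 0.05, against 2.76% in the data. Recovery in the data may therefore be lower. A binomial model that ignores the spread between replicates called 352 tiles, 167 higher and 185 lower. Leaving out young replicate 2 gave 2 calls and leaving out young replicate 3 gave 7, all higher in old sperm. Leaving out both leaves a single young library, which is then assumed to vary like the old ones, and gave 0.

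None of the following tiles passed; they are from the 5 higher and the 5 lower in old sperm with the smallest p, all on mm10. A tile in Camk1d, which encodes a calcium/calmodulin-dependent protein kinase (chromosome 2, 5379001 to 5380000, 19 CpGs), was at 55.2% ± 6.31 in young (SD, n = 3) and 79.7% ± 5.79 in old sperm (SD, n = 2), on 566 to 1348 reads per library. A tile in Gphn, which encodes the inhibitory synapse scaffold gephyrin (chromosome 12, 78351001 to 78352000), was at 37.8% ± 4.48 and 54.4% ± 3.68. Further tiles higher in old sperm were at Tmem267 (chromosome 13, 119488001 to 119489000), with 82.3% and 89.1%, and 18.7 kb from Gm40853 (chromosome 12, 19954001 to 19955000), with 86.5% and 95.1%. The tile at Tmem267 had 1016 to 1445 reads in young and 1802 to 2315 in old libraries. That near Gm40853 had 623 to 799 and 1375 to 1573. Whether reads from near-identical copies add to these tiles was not tested. The difference of 6.77 points at Tmem267 was 0.356 with no upper coverage limit and 2.86 with every CpG a library covers. Among those lower in old sperm, a tile in Aim2, encoding a sensor of cytosolic DNA (chromosome 1, 173420001 to 173421000), was at 83.0% ± 2.57 in young and 64.2% ± 2.38 in old sperm, on 135 to 211 reads per library. A tile in Slfn14, of the schlafen family (chromosome 11, 83284001 to 83285000), was at 85.9% ± 1.23 and 69.1% ± 2.16. Tiles in the noncoding genes Gm33104 (chromosome 10, 19494001 to 19495000) and Gm34162 (chromosome 3, 144164001 to 144165000) were at 68.1% and 69.0% in young and at 53.0% and 48.9% in old sperm. The last, 4.24 kb from Gm43568 (chromosome 3, 122634001 to 122635000), was at 67.5% and 47.3%. For each of these tiles the young and old libraries did not overlap, which a choice by the smallest p between the ages favours, so it is no support. Over all tiles this held for 17.1%, where chance gives 20%. Without young replicate 2 the Camk1d tile had an adjusted p of 0.0197, and without young replicate 3 the tiles at Camk1d and Gm40853 had 0.0398 and 0.0435 in the same model with limma-type moderation. The Gm40853 tile differed by 9.55 points there, under the 10 points that a call needs.

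Of 975172 single CpGs, 4 passed the same test, all higher in old sperm, each with an adjusted p of 0.0358 in the quasi-binomial model with limma-type moderation. One on the X chromosome at 154334489, 4735 bp from Samt2b, was at 48.3% ± 1.70 in young (SD, n = 3) and 79.8% ± 7.17 in old sperm (SD, n = 2), on 88 to 139 reads per library, and one on chromosome 13 at 79248170, 611436 bp from the nearest gene, was at 77.4% ± 4.17 and 94.2% ± 2.52. These CpGs were named after their values were seen. In the same model 23316 CpGs had an unadjusted p under 0.05. limma called 0 CpGs, with 41965 at an unadjusted p under 0.05, and at CpGs with at least 20 reads the count was also 0. Leaving out each library in turn gave between 0 and 140 calls, most of them lower in old sperm: 63 higher and 70 lower without young replicate 2, 55 and 85 without young replicate 3, 6 and 111 without old replicate 2, 0 and 2 without old replicate 1, and 0 without young replicate 1. With 1 old library left, it is assumed to vary like the young ones. The binomial model called 123 higher and 239 lower. The test recovered 29.0% of simulated CpGs lowered by 30 points in old sperm and 73.0% of those lowered by 50. Of the unchanged CpGs there, 4.264% and 4.315% had an unadjusted p under 0.05, against 2.39% in the data, so recovery in the data may be lower.

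Gene ends were used in place of promoters, because the annotation used here gives no strand. None of 4952 measured ends passed (smallest adjusted p = 1 in the moderated model; 95 ends had an unadjusted p under 0.05), and limma called 0, with 167 at an unadjusted p under 0.05. Simulated losses of 30 points in old sperm were recovered at 89.5% of ends. Of the unchanged ends there, 4.88% had an unadjusted p under 0.05, against 1.92% in the data, so recovery in the data may be lower. Of the 15 gene lists fixed before the data were examined, 14 had at least 2 measured ends, and none differed from other genes (limma camera, smallest adjusted p = 0.911 with the preset correlation and 0.914 with an estimated correlation). At the common CpGs no member passed when adjusted over the list alone or over all ends. At every CpG a library covers, 1 protocadherin gene passed when adjusted over the list alone and not over all ends: Pcdha7, at 84.3% ± 5.85 in young (SD, n = 3) and 49.4% ± 3.20 in old sperm (SD, n = 2), on 46 to 92 reads per library. With every listed CpG, a measure chosen after seeing the data, the same held for 1 developmental regulator, Hoxb1, at 89.8% ± 1.66 and 51.5% ± 11.0, on 31 to 81 reads. Their adjusted p over the list was 0.00765 and 0.0252 in the quasi-binomial model with limma-type moderation, and both were named after their values were seen. With every listed CpG Pcdha7 was at 63.5% ± 9.71 and 49.7% ± 1.63 and did not pass. The Hoxb1 value is of the end at 96365746 of chromosome 11; the other end, at 96368254, was at 74.6% ± 2.57 and 74.3% ± 6.98 with the common CpGs and at 75.6% ± 5.01 and 74.3% ± 6.59 at every CpG a library covers.

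Members of the lists are given as values. Among developmental regulators, 6 of 14 measured ends were higher and 8 lower in old sperm. The homeobox gene Lhx2 was at 89.7% ± 6.28 in young and 79.8% ± 7.64 in old sperm, Pax2 at 31.6% ± 16.6 and 22.5% ± 6.34, and Hoxa3 at 43.2% ± 18.3 and 34.2% ± 2.40. Of neurodevelopmental and autism-associated genes 4 of 8 were higher; Shank3, a synaptic scaffold gene, was at 71.1% ± 2.78 and 62.3% ± 5.61. Of 3 synaptic and neuronal genes 2 were higher; the other, Cacna1a, encoding a calcium channel subunit, was at 44.1% ± 2.88 and 33.7% ± 4.84. Of 6 insulin and metabolic genes 3 were higher; Igf1r was at 97.8% ± 2.33 and 92.1% ± 6.84, and Pparg at 18.7% ± 4.73 and 15.2% ± 0.031. Of 3 genes of the methylation machinery 1 was higher; Dnmt1, the maintenance methyltransferase gene, was at 60.2% ± 7.46 and 58.7% ± 4.48. Of 3 spermatid genes 1 was higher; Odf2, encoding a protein of the outer dense fibres of the tail, was at 34.9% ± 4.81 and 29.9% ± 2.93. Of 11 clustered protocadherin genes 4 were higher, and Pcdhga10 was at 35.0% ± 10.4 and 39.8% ± 13.1. The mean of this list differed by 0.0662 points with the common CpGs. At every CpG a library covers it differed by -2.60 points, and at every listed CpG by -3.46, where 35 of 53 were lower (exact permutation tests, p = 0.5 and 0.2). Of 130 olfactory receptor genes 69 were higher, and Olfr868 was at 72.4% ± 5.01 and 83.1% ± 2.52. At every CpG a library covers, 4 of the genes named here had the opposite order of the ages, Lhx2 with 73.7% in young and 74.2% in old sperm, Shank3 with 76.0% and 78.3%, Igf1r with 92.9% and 93.6%, and Pparg with 17.7% and 17.8%. Both measured housekeeping genes were lower in old sperm, Rplp0 at 34.6% ± 14.7 and 25.4% ± 11.3, and so were both leukocyte genes, Cd3e at 85.7% ± 6.85 and 84.7% ± 4.21.

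Lists that bear on cells other than sperm were also measured at every listed CpG. There 18 germline genes had a mean of 54.8%, 49.7% and 66.8% in young replicates 1 to 3 and of 58.9% and 59.4% in the old replicates. The 18 maternally imprinted loci, which are unmethylated in mature sperm at their control regions, were at 59.3%, 55.3% and 67.2%, and at 62.1% and 59.2%. These values are of the less methylated measured gene end and not of control regions or known promoters. Their level therefore does not measure a share of other cells. The 3 paternally imprinted loci were at 97.9%, 99.8% and 95.2%, and at 95.6% and 98.8%, and 15 epididymal epithelium genes at 79.9%, 91.8% and 78.9%, and at 87.7% and 84.0%. With the common CpGs 3 germline ends were measured, at 90.7%, 89.5% and 91.7% in young replicates 1 to 3 and at 94.6% and 93.7% in the old replicates, a difference of 3.53 points (young SD 1.08; exact permutation test, p = 0.1, the smallest possible) that was 3.61 at every CpG a library covers. The 4 maternally imprinted ends measured there were at 67.4%, 72.2% and 70.2%, and at 71.5% and 69.7%. Among them the germline helicase gene Ddx4 was at 83.5% ± 8.46 in young and 90.4% ± 1.89 in old sperm, and the imprinted gene Snrpn at 75.2% ± 8.90 and 77.6% ± 1.89. Of 5 epididymal genes with common CpGs 4 were higher; Adam7 was at 68.9% ± 14.7 and 75.5% ± 13.4.

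Whole gene regions, each gene with 1000 bp either side, were added after seeing the data. None of 17884 passed, with 261 at an unadjusted p under 0.05, and limma also called 0, with 529 at an unadjusted p under 0.05. Vomeronasal receptor genes, which encode pheromone receptors, were higher in old sperm in 92 of 116 measured regions, at 77.6% ± 0.223 (SD, n = 3) in young and 79.6% ± 1.19 (SD, n = 2) in old sperm (exact permutation test, p = 0.1, the smallest possible). limma camera gave this list an adjusted p of 9.69e-05 with the preset correlation; the adjusted p was 0.49995 with an estimated correlation, 0.0951 without young replicate 2 and 0.332 without old replicate 1. At the ends of the genes 12 of 30 were higher with the common CpGs (limma camera, adjusted p = 0.911), 20 of 36 at every CpG a library covers and 138 of 217 at every listed CpG. Examples of regions were Vmn2r55, at 79.5% ± 2.38 and 88.2% ± 5.85, and Vmn1r74, at 70.6% ± 6.62 and 79.1% ± 2.35. The regions of no other list passed, olfactory receptors among them at 85.4% and 85.9%.

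Old replicate 1 departed from the other libraries over a stretch of chromosome 8, and, less so, in 12 bins of 1 Mb between 82 and 115 Mb of chromosome 5. From 29000001 to 44000000 of chromosome 8, 495 of 15363 CpGs, 3.22%, were partly methylated (30 to 70%) in that library while at least 90% methylated in each of the other 4, against 18, 18, 31 and 26 such CpGs in the others. Mean methylation of the stretch was 86.0% in old replicate 1 and 88.8% to 90.3% in the other libraries. Without this stretch the count of called tiles was again 0.

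**Figure D3:**
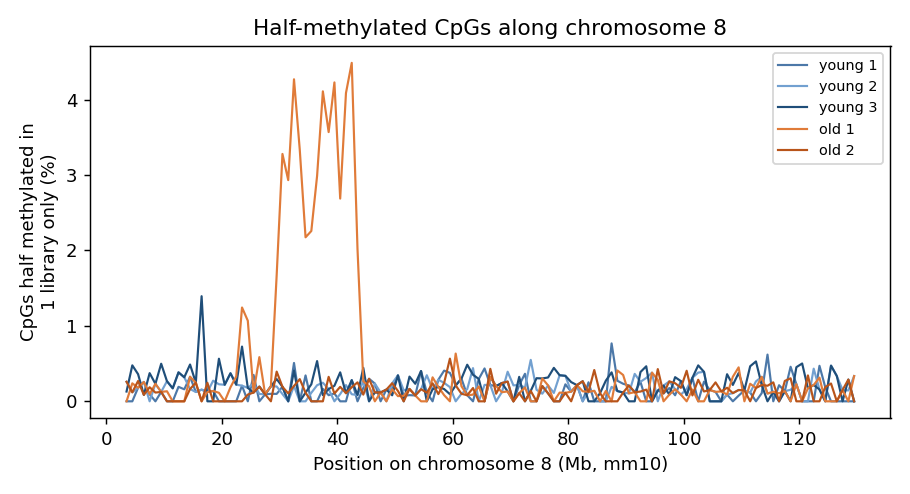
Share of CpGs (y axis, percent, in bins of 1 Mb) that are 30 to 70% methylated in 1 library and at least 90% in each of the other 4, along chromosome 8 (x axis, Mb, mm10), a line per library. The line of old replicate 1 reaches 4.49% between 29 and 44 Mb, where the other libraries together hold 18, 18, 31 and 26 such CpGs.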

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

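The tests of other cells, of conversion, of variants against the reference, of the level without partly methylated CpGs and of both explanations for the vomeronasal list were chosen only after the results were seen; those of depth, of stretches of lost methylation and of copy number were written down first. Mitochondrial DNA, listed in the data and used in no comparison of the ages, showed methylated reads in every library above the share that a count of 0 allows (3 reads of the total, 0.00196% to 0.00867%): 0.415%, 0.662% and 0.421% in young replicates 1 to 3, and 0.469% and 0.435% in old replicates 1 and 2. Incomplete conversion gives such reads too, so these shares do not show mitochondrial methylation.

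Young replicates 2 and 3 lay at opposite ends of the spread between libraries. Incomplete conversion would put the highest mitochondrial share in young replicate 3, which had 0.421% against 0.662% in young replicate 2, so the tables argue against it. Depth is argued against as well, since the gap between these libraries in tiles at 20 to 40% was 17.0 points at CpGs with at least 10 reads and 17.1 points at 20 reads, a ratio of 1.004. DNA of other cells stays open. With every listed CpG, germline gene ends in young replicate 3 lay 7.34 points above the highest of the other 4 libraries, and all 5 signs looked for were met. With the common CpGs 2 of 4 were, the low level of tiles over 90% and housekeeping ends not the highest. The germline and maternally imprinted lists, with 3 and 4 genes measured there, did not meet theirs. The low level of tiles over 90% is part of the pattern to be explained. With every listed CpG both lists lie at intermediate levels, where young replicate 3 was the highest library in tiles at large. In tiles at 40 to 60% in old sperm it was at 57.5%, against 45.9% to 51.6% in the others. The signs met therefore cannot decide. The share of reads on mitochondrial DNA was not among these signs. It was highest in young replicate 3 and lowest in young replicate 2. Young replicates 1 to 3 had 0.0842%, 0.0511% and 0.156%, and the old replicates 0.0546% and 0.0904%. What sets this share was not tested. Both libraries are of young mice, so no biological explanation was tested.

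Old replicate 1 carried a stretch of 15 Mb on chromosome 8 with many partly methylated CpGs. A candidate explanation is a heterozygous segment with variants against the reference, which reads as single CpGs of intermediate methylation. Of 285 comparable CpGs within 100 bp of one, 9.12% were partly methylated too (95% exact interval 6.05 to 13.1), 1.23 times the 7.40% among all 6691 comparable CpGs of the stretch, those at least 90% methylated in each of the other 4 libraries. Loss of methylation over stretches cannot be told apart on the bound written first, which the data met (9.12% against 6.75% near such CpGs elsewhere). That bound ignored the much lower share elsewhere, 0.336%, against which near CpGs stood at 20.1 times (a comparison made afterwards). Without the partly methylated CpGs old replicate 1 was still at 87.0% in the stretch, against 88.6% in the lowest of the other libraries. Only CpGs at least 90% methylated in each of the other 4 libraries could count as partly methylated. At all other CpGs old replicate 1 differed from those libraries by -2.34 points in the stretch and by 1.41 on the rest of the chromosome. These CpGs could hold variants too, so the lower level outside the partly methylated CpGs cannot tell the explanations apart. Loss of 1 copy was tested on reads alone, which cannot decide. The reads of the stretch were 0.790 times those of the other libraries, between the bounds of 0.65 and 0.8 set beforehand. Whether such a loss would give partly methylated CpGs was not tested. Age is untested, as the stretch was in 1 of the 2 old libraries.

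Vomeronasal receptor regions were higher in old sperm. The spread between young replicates 2 and 3 stays open as a cause. The pair differed by 0.186 points in these regions against 2.05 between the ages. A list mean can hide the spread, as its direction turns with the level. In tiles within 200 kb of the genes the pair stood at 59.5% and 65.4% at intermediate levels (20 to 80%). In those over 80% it stood at 91.6% and 90.1%. The median log2 odds difference was 0.16 in all libraries and with the germline list as a covariate (limma camera, preset correlation, adjusted p = 9.69e-05 and 0.00198). It was 0.16 without both libraries of the pair, 0.0962 without old replicate 1 and 0.248 without old replicate 2. With an estimated correlation the list passed neither with the covariate (adjusted p = 0.832) nor without it (0.49995), and in tiles within 200 kb of the genes, a wider set, the pair stood at 77.7% and 79.3% with old replicate 2 at 79.2%, so for those tiles this spread stays open. Reads piled on collapsed copies cannot be told apart either: in tiles within 200 kb of these genes the difference was 1.24 points below the median coverage and 1.44 points above it, but the ages overlapped below it (exact permutation test, p = 0.3). Age stays among the open explanations.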

How the results depend on the processing

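The alternatives that leave out both young replicates 2 and 3, use another dispersion prior, gene regions, every listed CpG, a germline covariate or leave out the chromosome 8 stretch were chosen after seeing the data. Called tiles numbered 0 in every setting except the binomial model (352), every CpG a library covers (1) and the libraries left out in turn (0 to 7). Called gene ends numbered 0 in every setting except the binomial model (23). The 4 called CpGs depended on the processing: the binomial model gave 362 (123 higher, 239 lower in old sperm), and unmoderated dispersion, limma with or without centring, at least 20 or 5 reads, no upper limit, the stricter threshold, the prior from all CpGs and leaving out both young replicates 2 and 3 each gave 0, while leaving out 1 library gave 0 to 140, with mostly lower calls (6 higher and 111 lower without old replicate 2). Without both, the lone young library is assumed to vary like the old ones. Which of the 4 CpGs were called elsewhere was not counted, and the cause of these changes was not tested. No gene list passed by gene ends in any setting; by gene regions 1 passed, and 0 with an estimated correlation, with 0 to 1 when a library was left out. The difference at gene ends was 0.497 points when weighted by coverage and 1.09 at every CpG a library covers, against 0.0978, and that of the germline list 2.06 at every listed CpG, against 3.53; the cause was not tested. Without young replicate 3 the global difference was -0.0186 points, that of gene bodies -0.334 and of autosomes -0.0834, none of which passed a test. In the alternatives computed for single tiles (not limma, other tile widths or thresholds), the tiles chosen by the rule kept their direction. Of these values 144 had an adjusted p of at least 0.05 and 14 were below it. Those 14 all came from the binomial model or from leaving out young replicate 2 or 3. The tiles were chosen for the smallest p in these same libraries, so a kept direction is no support. At the depth of these libraries 73.0% of simulated CpGs and 99.5% of simulated tiles lowered by 50 points in old sperm were recovered. Gains were not simulated, and depth was not varied there. Small unadjusted p-values were rarer in the data than among unchanged simulated features, so recovery in the data may be lower.

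Replicate numbers 1 and 2 occur at both ages, but nothing ties the libraries that share one, and the correlations of their deviations from the group means were 0.0182 and -0.0462. With the replicate number as a block, young replicate 3 has no old library of its number and adds nothing to the comparison of the ages. Called CpGs then numbered 128 (42 higher, 86 lower) in the quasi-binomial model and 0 with limma, whose smallest adjusted p was 0.958. Called tiles and gene ends numbered 0. The global difference was -0.0186 points, the same as without young replicate 3 and within the spread between replicates.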

Other observations

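The comparisons of other splits and of regions below were all chosen after seeing the data. Of the 10 splits of the 5 libraries into 3 and 2, the real one gave 0 called tiles and the highest other, young replicate 3 with old replicate 2 against the rest, gave 101; in the binomial model the real split gave 352 and that split 3039, which points to a structure of the libraries other than age. Several other splits also gave 0 called tiles in the quasi-binomial model, so a count of 0 does not set the real one apart. Tiles with an unadjusted p under 0.05 in that model numbered 3721 in the real split and 2862 to 12434 in the others. With 10 splits, a result cannot reach a share under 0.05.

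Mean methylation was higher in old sperm on every chromosome except 8, by 2.69 points on Y, 0.612 on X and 0.557 on chromosome 7 (exact permutation tests, p = 0.3, 0.3 and 0.2). The difference on chromosome 8 was -0.0884 points, and 0.0947 without old replicate 1, where that on chromosome 15 was -0.0157. On the autosomes this direction rested on young replicate 3, the lowest library on all 19: without it old sperm was higher on 3 and lower on 16, while the differences were 0.297 points on chromosome 7, 0.912 on X and 3.82 on Y. Tiles within 200 kb of olfactory receptor genes were at 86.7% ± 0.142 (SD, n = 3) in young and 87.3% ± 0.308 (SD, n = 2) in old sperm, and both old libraries lay above all 3 young ones (exact permutation test, p = 0.1). On the Y chromosome 75.2% of 888 tiles were higher in old sperm, on the X chromosome 56.5% of 3374, near vomeronasal receptor genes 64.5% of 1885, and among the other autosomal tiles 52.8% of 125923. In the first 3 of these the libraries of both ages overlapped (exact permutation test of the mean, p = 0.3, 0.5 and 0.3). Tiles are not independent, and these shares have no test.

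Old replicate 1 had 32 bins of 1 Mb in which over 1% of CpGs were partly methylated (30 to 70%) in that library alone, against 0, 1 and 1 in the young libraries and 1 in old replicate 2. Apart from 17 bins on chromosome 8, 12 lay on chromosome 5 between 82 and 115 Mb.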
